A study of Homo sapiens with 12 samples.

How the data were processed

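Expression was profiled in 2 human cell lines that carry the JAK2V617F mutation, HEL and UKE1, each cultured for 6 h without drug or with 250 nM ITF2357. ITF2357 (givinostat) inhibits histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. Each of the 4 groups held 3 Affymetrix Gene ST arrays, 12 in all, which the series describes as independent triplicates. The p-values measure the spread between these samples; nothing more is said of how the cultures were kept apart. Per the labels' protocols, UKE1 medium also held horse serum and hydrocortisone, which HEL medium did not.

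Per the submitters' processing notes, the authors used Affymetrix Expression Console with RMA (background correction, quantile normalization and summary of the probes of each transcript cluster). The versions are not given in the sources used here. The deposited values are read as log2 from their range, since no label states the base. They lay between 1.26 and 14.36 on the 12 arrays, with array medians between 6.41 and 6.50. Near-identical distributions on all arrays were also taken to mean that the arrays were normalized together. The table carries no detection flag, so no gene was called absent, and the number of arrays limits the precision.

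The table held 33297 rows. GEO's platform annotation gave 1 gene symbol for 19460 of them, several for 1754 and listed no gene for 12083. Rows with several symbols or none stayed out of the main tests. Of 769 genes with more than 1 row, the row with the highest mean over all arrays was kept, which left 18417 genes. The gene IDs of 19429 rows were found in the RefSeq gene table of assembly GRCh38.p14, and no symbol needed updating. That table served only for names and for which genes neighbour each other; no coordinates are given, since the array annotation names no genome build. List members without a row of a single symbol were not analysed here.

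A model with 1 mean per group was fitted to the log2 values of all 12 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), so that the groups shared 1 estimate of the spread with 8 residual degrees of freedom. The contrasts were ITF2357 minus untreated in HEL and in UKE1, their average, the difference between the responses (UKE1 minus HEL), and untreated UKE1 minus untreated HEL. Tests were two-sided, with Benjamini-Hochberg adjustment over the 18417 genes and a threshold of 0.05; all adjusted p-values for genes below come from limma. A gene rose, fell or changed when it passed that threshold. Errors of log2 changes are standard errors of the fit, and errors of group means are SD over 3 arrays.

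Before the data were examined, 31 gene lists with 646 members were written down, of which 577 were measured. They cover blood cell lineages, other cell types, JAK-STAT signalling, the cell cycle, apoptosis, chromatin, stress responses and metabolism. Each list was tested against all other genes with camera (preset inter-gene correlation of 0.01), adjusted over the 31 lists of a contrast. Camera with an estimated correlation and fry were run beside it. Of the list calls, none of 10 in HEL, 3 of 14 in UKE1, 0 of 9 for the difference and 0 of 11 between the untreated lines held with an estimated correlation. The smallest adjusted p with an estimated correlation was 0.0588, 0.0352, 0.133 and 0.0764 in these contrasts. Median, mean and camera direction differed in sign for 21 of 124 pairs of list and contrast, none of them called, with a smallest camera adjusted p of 0.205.

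The genes named were set by a rule fixed at the same time. For each drug contrast these were the 10 largest increases and the 10 largest decreases past the threshold whose 3 treated arrays lay beyond the 3 untreated ones. The difference between lines gave 5 each way, and the untreated lines 10 each way. The rule added up to 4 members of each list with the smallest adjusted p, and NFE2, MYB, TAL1, GATA1, JAK2, STAT5A, BCL2L1, CDKN1A and MYC, and 1 more gene that is not reported here. Where 5 or fewer members of a called list moved against the rest, they were named after their values were seen. Uncharacterised loci, small RNAs and sex-specific genes were counted in totals but not named. Every gene that the rule named for a drug contrast, and that is said below to have risen or fallen in it, had 3 treated arrays beyond all 3 untreated arrays of the line. For genes named after their values were seen, or by the rule for another contrast, this was not checked.

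The fit was tested on simulated arrays of the 18417 genes, 200 of them changed. At log2 changes of 0.25, 0.5 and 1, 16.2%, 75.8% and 98.5% of changed genes were recovered in HEL, and 20.6%, 71.2% and 98.5% in UKE1. There were 7 false calls in HEL (5.3% of calls) and 6 in UKE1 (4.5%). In the data 42.4% and 44.3% of genes were called in these contrasts, far more than were changed in the simulation. The recovery rates therefore do not give the sensitivity of the real fit. In a simulation of the HEL contrast with 1 list shifted by 0.5, camera called that list and 0 of the 30 others. The simulated noise was drawn separately for each gene. This run therefore cannot show how camera behaves where the members of a list vary together.

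The alternatives tried were 2 filters on dim genes, quantile normalization, centring of each array on its median, the mean of a gene's rows, all rows tested singly, an intensity trend with a robust prior, array weights, fits of 6 arrays alone, the replicate number as a block, stricter thresholds and leaving out each array in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.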

Results

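Gene expression was measured in HEL and UKE1 cells, established lines labelled as erythroleukemia cells with the JAK2V617F mutation, which makes the kinase JAK2 active without cytokine. The series' title names an effect of the histone deacetylase inhibitor ITF2357 on key haematopoietic genes, on proliferation, differentiation and apoptosis. The comparisons are therefore ITF2357 against no drug in each line, the responses of the lines against each other, and the untreated lines. Arrays of one group correlated at r = 0.994 to 0.996 over all rows, arrays of one line with and without drug at 0.982 to 0.985, and arrays of different lines at 0.928 to 0.943. The median absolute log2 difference between 2 arrays of a group was 0.094 to 0.134.

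In HEL cells, ITF2357 lowered NFE2, MYB and TAL1, transcription factors of blood cell formation, and STAT5A, a main target of JAK2. NFE2 went from a log2 level of 10.52 ± 0.078 to 9.14 ± 0.13 (SD, n = 3), a fall to 2.61-fold less (adjusted p = 7.05e-09). MYB fell 2.65-fold, from 11.24 ± 0.044 to 9.83 ± 0.0145 (adjusted p = 1.74e-09), TAL1 fell 2.17-fold (adjusted p = 7.48e-08) and STAT5A fell 2.02-fold (adjusted p = 2.02e-08). The cell cycle inhibitor CDKN1A rose 2.01-fold (adjusted p = 3.01e-08), while MYC fell 1.73-fold and the survival gene BCL2L1 fell 1.74-fold. GATA1, a master regulator of erythroid cells, fell 1.41-fold (adjusted p = 0.000113), and the log2 change of JAK2 itself was 0.10 ± 0.069 (SE, adjusted p = 0.263).

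Over all genes in HEL, 4157 rose and 3659 fell, together 42.4% of the 18417 tested; 436 rose and 251 fell at least 2-fold. Which direction held more genes depended on the scaling, with 3918 higher and 4014 lower after quantile normalization and 3621 and 4604 after centring each array on its median. The treated and untreated arrays did not overlap for 49% of genes, against 10% by chance. The largest increases were those of GLRX (6.53-fold), a glutaredoxin, and STAT4 (6.29-fold), a signal transducer of cytokine receptors. They were followed by ELOVL4 (6.14-fold), an elongase of very long fatty acids, GALM (5.68-fold), a galactose mutarotase, DENND2C (5.57-fold) and SMARCA1 (5.49-fold), a chromatin remodelling ATPase. TMEM243, PFN2, SERPINB9, which inhibits granzyme B, and ARHGAP29 rose by 5.42-fold, 4.89-fold, 4.67-fold and 4.67-fold. The largest decreases were those of the keratin KRT79 (6.63-fold), UTP20 (5.45-fold), a factor of ribosome assembly, LANCL2 (4.96-fold), GPR85 (4.67-fold) and PIGW (3.64-fold), an enzyme of GPI anchor synthesis. GP6, the platelet collagen receptor, fell 3.43-fold, RSAD2, an interferon-induced antiviral gene, 3.34-fold, PLD6 3.31-fold, TGM5 3.29-fold and ITLN2 3.23-fold.

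**Figure D1:**
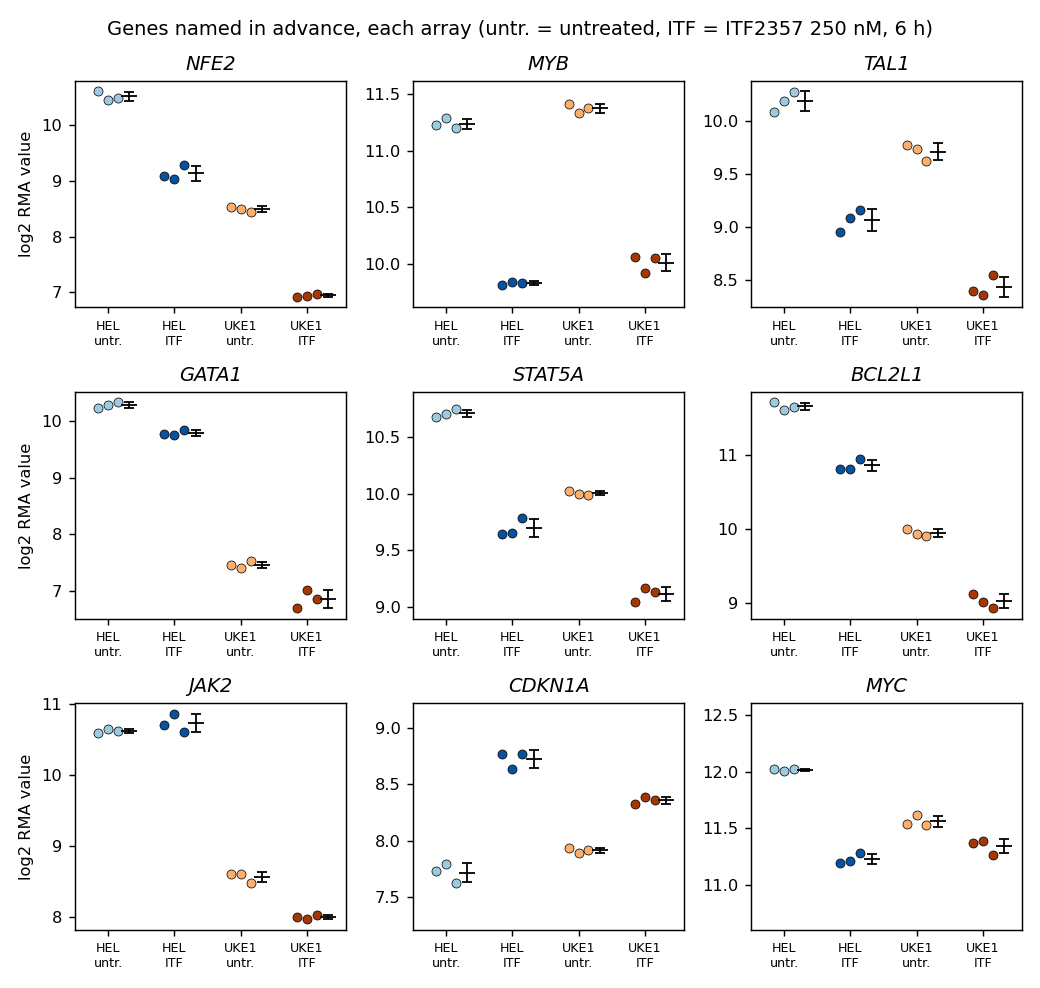
Log2 RMA values (vertical axes, whose ranges differ between genes) of 9 genes named in advance, in untreated (pale) and ITF2357-treated (dark) HEL and UKE1 cells; each point is 1 of 3 arrays, and the bar beside the points is the mean with its SD. NFE2, MYB, TAL1, GATA1, STAT5A, BCL2L1 and MYC were lower and CDKN1A higher with drug in both lines, while JAK2 was lower with drug in UKE1 and had a log2 change of 0.10 in HEL.

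Genes of MYC-driven growth and ribosome biogenesis fell as a group in HEL: of 27 measured, 0 rose, 23 fell and 4 were not called (24 fell when adjusted over the list alone). UTP20 (-2.45), RRS1 (-1.38), SRM (-1.29) and WDR43 (-1.18, all log2) led the list (camera adjusted p = 1.19e-13; adjusted p = 0.0588 with an estimated correlation). Of 22 megakaryocyte and platelet genes, 13 fell, 8 were not called and 1, CD9 (0.86), rose, with the same counts when adjusted over the list alone. Besides GP6, the list held THBS1 (-1.47), ANGPT1 (-1.40) and the von Willebrand receptor chain GP1BA (-0.92); camera gave an adjusted p = 0.000172, and an adjusted p = 0.106 with an estimated correlation. Of 26 haematopoietic transcription factors, 12 fell, 5 rose and 9 were not called (14 fell and 5 rose when adjusted over the list alone). CBFA2T3, a corepressor of erythroid and megakaryocyte genes, fell by 1.16, whereas CEBPB (0.47), ERG (1.08), BCL11A (0.63), MEIS1 (0.58) and LDB1 (0.54) rose. This list's camera adjusted p was 0.0426 (adjusted p = 0.368 with an estimated correlation). It is not independent evidence, since the series' title speaks of key haematopoietic genes and the study is known to have reported on NFE2 and MYB.

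Mitotic genes also fell in HEL. Of 30 G2/M genes, 15 fell, 4 rose and 11 were not called (18 fell and 5 rose when adjusted over the list alone; camera adjusted p = 0.00935, adjusted p = 0.449 with an estimated correlation). Cyclin B1 (CCNB1, -0.82), PLK1 (-0.64), MKI67 (-0.64) and UBE2C (-0.60) were the clearest, while CDC20 (0.22), CDC25C (0.48), KIF11 (0.40) and NEK2 (0.50) rose. Of 37 G1/S and replication genes, 18 fell, 7 rose and 12 were not called, with the same counts when adjusted over the list alone (camera adjusted p = 0.0742). These included CCND3 (-0.70), the replication factor GINS3 (-0.83), the glycosylase UNG (-0.68) and MCM5 (-0.55).

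Death receptor, caspase and p53 target lists were called upwards in HEL. Of 17 death receptor and caspase genes, 8 rose, 0 fell and 9 were not called, with the same counts when adjusted over the list alone. They were led by the TRAIL receptor TNFRSF10B (1.96), CASP10 (1.62), APAF1 (1.54), which assembles the apoptosome, and the decoy receptor TNFRSF10D (0.69). Camera gave this list an adjusted p = 0.00825 and an adjusted p = 0.368 with an estimated correlation. Of 22 p53 target genes, 14 rose, 3 fell and 5 were not called, and these counts were the same when adjusted over the list alone (camera adjusted p = 0.00935, adjusted p = 0.368 with an estimated correlation). TP53INP1 (1.39) and SESN1 (1.03) rose, while MDM2 (-0.67), which marks p53 for degradation, PLK3 (-0.39) and AEN (-0.96) fell. Among 13 pro-apoptotic BCL2 family genes 6 rose, 0 fell and 7 were not called, likewise when adjusted over the list alone, with BCL2L11 (1.03), BMF (0.70), BNIP3L (0.63) and BAD (0.63) in front (camera adjusted p = 0.107). Of 7 anti-apoptotic genes 3 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.48); BCL2L1 (-0.80), XIAP (-0.67) and BIRC2 (-0.21) fell and MCL1 (0.29) rose.

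The remaining HEL lists with a camera call all went up. Of 16 cholesterol synthesis genes 10 rose and 0 fell, among them LSS (0.81), MVK (0.64), DHCR7 (0.57) and SQLE (0.40); the adjusted p was 0.00496, and adjusted p = 0.368 with an estimated correlation. Of 13 replication-independent and polyadenylated histone genes 9 rose and 1, H2BC4 (-0.29), fell (camera adjusted p = 0.0265, adjusted p = 0.432 with an estimated correlation). H1-10 (0.85), H2BC5 (0.54), H1-2 (0.51) and H3-3B (0.34) had the smallest adjusted p-values among them. Of 14 genes often raised by such inhibitors 7 rose and 0 fell, including CDKN1A and the actin-severing GSN (0.42), at an adjusted p = 0.0351 (adjusted p = 0.413 with an estimated correlation). For these 3 lists the counts were the same when adjusted over the list alone. Metallothioneins, metal-binding proteins of near-identical sequence that arrays separate incompletely, rose in 6 of 8 cases and fell in 0 (7 rose when adjusted over the list alone). MT1X (0.63), MT1E (0.60), MT1G (0.54) and MT2A (0.49) were the clearest (camera adjusted p = 0.00825, adjusted p = 0.197 with an estimated correlation).

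In UKE1 cells the same transcription factors fell. NFE2 went from 8.49 ± 0.052 to 6.94 ± 0.030 (SD, n = 3), 2.93-fold lower with ITF2357 (adjusted p = 2.15e-09); MYB was 2.58-fold lower (adjusted p = 1.22e-09) and TAL1 2.42-fold lower (adjusted p = 1.86e-08). STAT5A fell 1.85-fold, BCL2L1 1.90-fold and GATA1 1.52-fold, with adjusted p = 5.05e-08, 8.9e-08 and 1.7e-05. JAK2 fell 1.48-fold (adjusted p = 1.14e-05) and MYC 1.16-fold (adjusted p = 0.00664), and CDKN1A rose 1.36-fold (adjusted p = 4.77e-05).

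Over all genes in UKE1, 4045 rose and 4115 fell, 44.3% of those tested, of which 403 and 416 changed at least 2-fold. Arrays did not overlap for 53.9% of genes, against 10% by chance. MYBL1, a relative of MYB, rose 7.33-fold, the neuronal serpin SERPINI1 7.22-fold and SAMHD1, which breaks down deoxynucleotides, 5.73-fold. Increases of 5.71-fold to 4.35-fold followed for RGL1, TMOD2, GRAMD1C, CCDC148, STAT4, TRIP10 and RGS2, an inhibitor of G protein signalling. UTP20 fell 6.21-fold, the blood cell phosphatase PTPN7 6.07-fold, the lipid transporters ABCA6 and ABCA9 5.97-fold and 5.90-fold, and the C-type lectin CLEC4D 5.60-fold. OR52N5, ANGPT1, a ligand of the receptor TEK, KCNQ5, CCDC26 and JADE2 fell by 5.05-fold, 4.87-fold, 4.57-fold, 4.54-fold and 4.50-fold.

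The megakaryocyte and ribosome lists fell in UKE1 too. Of 22 megakaryocyte and platelet genes 0 rose, 18 fell and 4 were not called, also when adjusted over the list alone, including RAB27B (-1.10), P-selectin (SELP, -0.98) and GP1BA (-0.74); camera gave an adjusted p = 2.9e-08, and an adjusted p = 0.0352 with an estimated correlation. Of 27 MYC and ribosome biogenesis genes 24 fell and 0 rose (25 fell when adjusted over the list alone), with RRS1 (-1.30), NOP16 (-1.24) and PUS7 (-1.13) behind UTP20 (camera adjusted p = 1.03e-10, adjusted p = 0.0396 with an estimated correlation). Of 26 haematopoietic transcription factors 13 fell, 12 were not called and 1, CEBPB (0.78), rose, the same when adjusted over the list alone; SPI1, a regulator of myeloid cells, fell by 0.96. This list had a camera adjusted p = 0.000126 (adjusted p = 0.0854 with an estimated correlation). Of 14 stem and progenitor surface genes 6 fell and 1, PROCR (0.25), rose (7 fell and 1 rose when adjusted over the list alone). CD34 (-1.19), ENG (-0.65) and MLLT3 (-0.60) were among those that fell (camera adjusted p = 0.0475, adjusted p = 0.139 with an estimated correlation). Despite the list's name, not all of its members code for surface proteins, MLLT3 and the ligand ANGPT1 among them.

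Cell cycle genes fell in UKE1 as well. Of 37 G1/S and replication genes 25 fell, 5 rose and 7 were not called (27 fell and 5 rose when adjusted over the list alone; camera adjusted p = 5.21e-06, adjusted p = 0.176 with an estimated correlation). GINS3 (-1.76), E2F8 (-1.20), MCM7 (-0.99) and UNG (-0.97) fell, whereas the cyclins CCNE1 (0.96) and CCNE2 (0.66) rose with CDC6 (0.37), CDT1 (0.19) and SLBP (0.38). Of 30 G2/M genes 16 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 0.00209, adjusted p = 0.404 with an estimated correlation). PLK1 (-1.24), cyclin A2 (CCNA2, -0.9955), KIF20A (-0.76) and UBE2C (-0.66) fell, and TOP2A (0.25), CDC25C (0.45), KIF11 (0.32) and NEK2 (0.68) rose. Of 23 homologous recombination and damage response genes 9 fell and 3 rose (11 fell and 3 rose when adjusted over the list alone), with NBN (-1.08), CHEK1 (-0.60), BRIP1 (-0.58) and BRCA1 (-0.54) lower and FANCB (0.26), CHEK2 (0.42) and BLM (0.34) higher (camera adjusted p = 0.0451, adjusted p = 0.597 with an estimated correlation).

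Interferon response genes fell in UKE1: 15 of 25 fell, 2 rose and 8 were not called (16 fell and 3 rose when adjusted over the list alone). IFI44L (-1.95), IFIT3 (-1.57), TRIM22 (-1.12) and the transcription factor IRF9 (-0.86) fell, and IFI6 (0.37) and IRF1 (0.42) rose (camera adjusted p = 0.000778, adjusted p = 0.129 with an estimated correlation). Of 13 pro-apoptotic BCL2 family genes 7 rose, 2 fell and 4 were not called (8 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.0172, adjusted p = 0.107 with an estimated correlation). BMF (1.39), BCL2L11 (1.08) and PMAIP1 (0.85) rose, and BID (-0.51) and BAX (-0.31) fell. Death receptor and caspase genes went both ways, 7 up and 5 down of 17, also when adjusted over the list alone (camera adjusted p = 0.588), with APAF1 (1.18) and CASP10 (0.79) up and FAS (-1.14) down.

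Upward calls in UKE1 included all 8 metallothioneins, also when adjusted over the list alone, with MT1X (1.15), MT1G (0.82), MT2A (0.78) and MT1F (0.68) in front (camera adjusted p = 7.38e-05, adjusted p = 0.0396 with an estimated correlation). Of 19 immediate early genes 11 rose and 0 fell, likewise when adjusted over the list alone, led by JUN (1.28), DUSP5 (1.00), FOS (0.93) and ZFP36 (0.83); the adjusted p was 0.000843, and adjusted p = 0.126 with an estimated correlation. Of 13 histone genes 9 rose and 1, H2AZ1 (-0.34), fell, with H1-10 (1.69), H2BC21 (1.17), H2AJ (1.06) and H3-3B (0.95) in front (adjusted p = 0.00256; adjusted p = 0.271 with an estimated correlation). Of 14 genes often raised by such inhibitors 8 rose and 1, THBD (-0.70), fell; DHRS2 (2.09) and TXNIP (0.94) were among those that rose (adjusted p = 0.0127, adjusted p = 0.271 with an estimated correlation). Glucocorticoid-responsive genes rose in 8 of 11 cases and 1, ZBTB16 (-0.60), fell, with SGK1 (1.69), DDIT4 (2.07), TSC22D3 (0.93) and PER1 (0.73) up. Camera gave them an adjusted p = 0.00523 and an adjusted p = 0.0849 with an estimated correlation. Hydrocortisone was in this line's medium in both conditions. In HEL, whose medium held none, 5 of the 11 rose and 2 fell (camera adjusted p = 0.161). The difference of this list between the lines was not called (camera adjusted p = 0.14). For the last 3 lists the counts were the same when adjusted over the list alone.

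**Figure D2:**
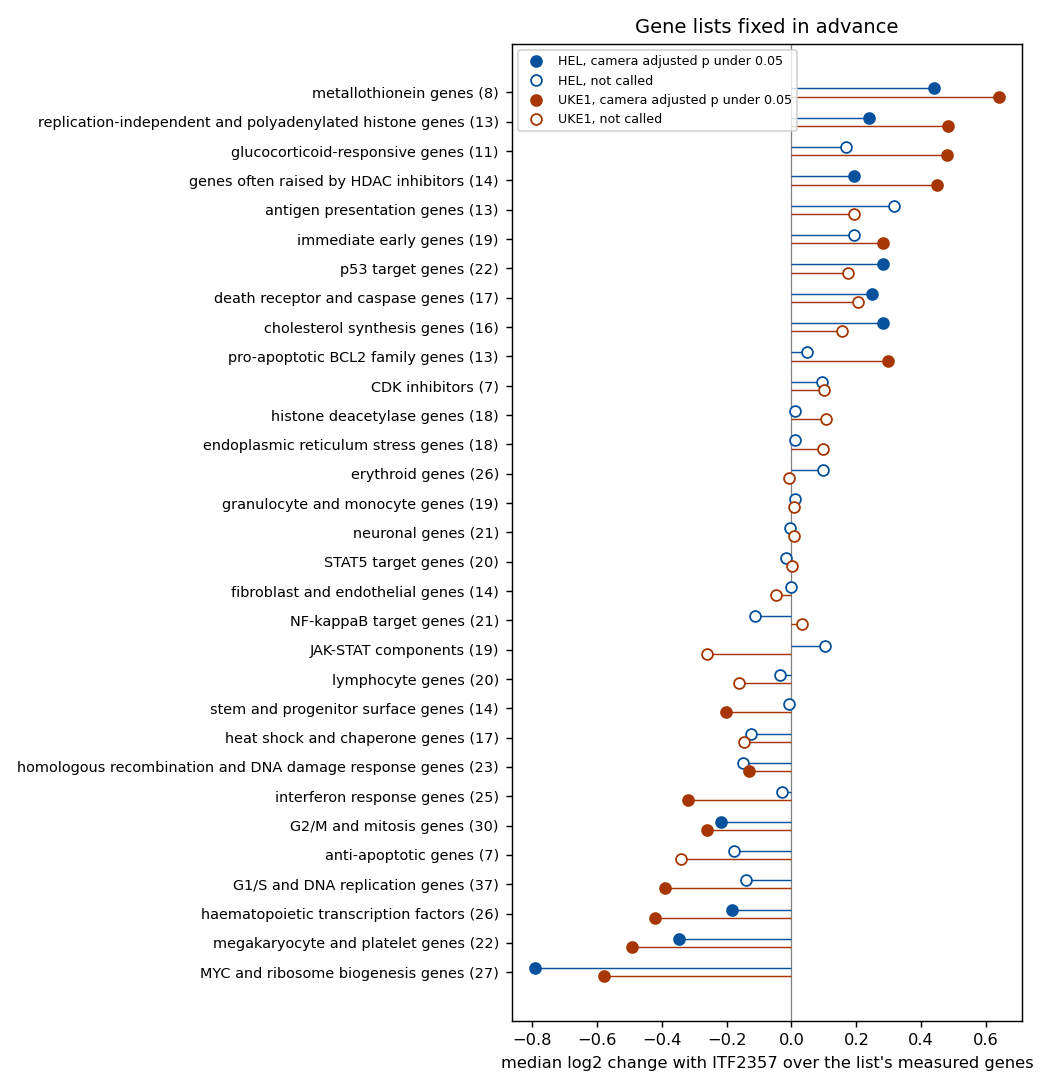
Median log2 change with ITF2357 (horizontal axis) of the measured genes in each of 31 gene lists (vertical axis, number of genes in brackets), in HEL (blue) and UKE1 (brown); filled points are lists with a camera adjusted p under 0.05. MYC and ribosome biogenesis genes had the lowest medians, -0.79 in HEL and -0.58 in UKE1, and metallothioneins the highest, 0.44 and 0.64.

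Both lines shared a large part of the response. Of the genes tested, 2583 rose in both lines and 2385 fell in both, 4968 in all, against 913 and 817.5 for independent lists of these lengths. The drug arrays and untreated arrays of a line enter only that line's log2 changes, but the estimate of the spread was shared between the lines. A gene with a small spread is thus more readily called in both lines. The counts for independent lists are therefore not a strict baseline, and how much the shared spread adds to the overlap was not tested. Log2 changes correlated across genes at Pearson's r = 0.650 and Spearman's rho = 0.583 over all genes, which are not independent replicates, and 67.6% of genes had the same sign. Among the 1229 genes that changed at least 2-fold in 1 line or more, r was 0.731 and 90.9% had the same sign. UTP20, NFE2, MYB, TAL1 and RSAD2 fell and STAT4 rose in both lines, and their responses had differences of -0.19, -0.17, 0.04, -0.16, 0.04 and -0.48 between lines, none past the threshold (adjusted p = 0.308, 0.281, 0.773, 0.342, 0.863 and 0.0558). The average response over both lines was past the threshold for 9387 genes.

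**Figure D3:**
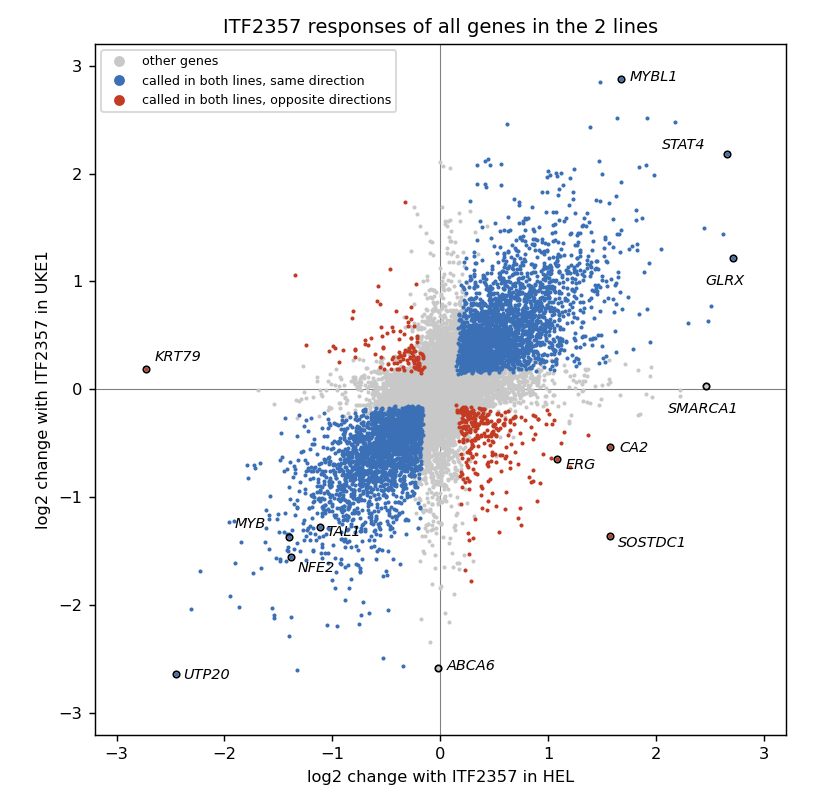
Log2 change with ITF2357 in HEL (horizontal axis) against that in UKE1 (vertical axis) for the genes tested, sex-specific genes left out; blue genes were called in both lines in the same direction, red ones in opposite directions, and circles mark named genes. Across all genes r was 0.650; UTP20 lies low and STAT4 high in both lines, while KRT79 and SOSTDC1 lie in the quadrants of opposite change.

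The lines also responded differently. The interaction was past the threshold for 4395 genes, 1854 with a more positive and 2541 with a more negative change in UKE1. Of the 4395, 1329 had changed the same way in both lines, 2590 in 1 line only, 386 in opposite directions and 90 in neither. Opposite change was rarer than for independent lists of these lengths, which are not a strict baseline. Against 928.8 for such lists, 275 genes rose in HEL and fell in UKE1, and 111 did the reverse against 803.6. The excess of negative differences also depended on the scaling: 42.2% of the 4395 genes had a positive difference as deposited, 49.9% after quantile normalization and 51.4% after median centring. KRT79 fell by 2.73 in HEL and rose by 0.19 in UKE1, and SOSTDC1, an inhibitor of BMP and Wnt signals, rose by 1.57 in HEL and fell by 1.36 in UKE1. ERG, which marks stem cells and megakaryocytes, rose by 1.08 in HEL and fell by 0.64 in UKE1 (difference -1.72, adjusted p = 7.32e-07). The carbonic anhydrase CA2 rose by 1.57 in HEL and fell by 0.53 in UKE1 (difference -2.10, adjusted p = 9.55e-08). JAK2 had a difference of -0.67 (adjusted p = 0.000247), CDKN1A of -0.56 (adjusted p = 0.000455) and MYC of 0.57 (adjusted p = 0.000222).

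Of the 31 lists, 5 had a more negative response in UKE1. Interferon response genes were lower in 15 of 25 cases and higher in 0 (16 lower and 1 higher when adjusted over the list alone), with IFIT1 (-1.79), GBP2 (-1.48), TRIM22 (-1.02) and RIGI (-0.94) the clearest. Their camera adjusted p was 0.000223 (adjusted p = 0.248 with an estimated correlation). G1/S and replication genes were lower in 17 of 37 and higher in 0 (19 and 5 when adjusted over the list alone), among them CCND1 (-0.99) and CCND2 (-0.89), at an adjusted p = 0.000686 (adjusted p = 0.372 with an estimated correlation). Stem and progenitor surface genes were lower in 8 of 14, also when adjusted over the list alone, including THY1 (-1.20), MLLT3 (-1.08), ANGPT1 (-0.88) and CD34 (-0.74); the adjusted p was 0.00217, and adjusted p = 0.133 with an estimated correlation. Death receptor and caspase genes were lower in 9 of 17 and higher in 1, TNFRSF21 (10 and 2 when adjusted over the list alone), with TNFRSF10B (-1.75), FAS (-1.30) and CASP6 (-1.10) in front (adjusted p = 0.00458, adjusted p = 0.35 with an estimated correlation). The p53 targets were lower in 6 of 22, also when adjusted over the list alone, with DDB2 at -0.76 (adjusted p = 0.0153; adjusted p = 0.363 with an estimated correlation).

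A further 4 lists had a more positive response in UKE1. Immediate early genes were higher in 7 of 19 and lower in 1, KLF10 (10 and 2 when adjusted over the list alone), with JUN (1.16), DUSP2 (0.73), JUND (0.39) and FOSL1 (0.38) the clearest (adjusted p = 0.0265, adjusted p = 0.363 with an estimated correlation). NF-kappaB targets were higher in 5 of 21 and lower in 0, also when adjusted over the list alone: TNFAIP3 (1.03), IL6 (0.47), CXCL8 (0.40), RELB (0.28) and NFKB2 (adjusted p = 0.0277, adjusted p = 0.35 with an estimated correlation). Metallothioneins were higher in 4 of 8 (5 when adjusted over the list alone; adjusted p = 0.0249, adjusted p = 0.345 with an estimated correlation), led by MT1F (0.69) and MT1X (0.51). MYC and ribosome biogenesis genes were higher in 6 of 27 and lower in 1, NOLC1, likewise when adjusted over the list alone, with SRM (0.71), MYC (0.57) and NOP2 (0.52) less lowered in UKE1 (adjusted p = 0.0436, adjusted p = 0.501 with an estimated correlation).

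Without drug, the lines differed in 67.7% of the genes, with 6132 higher and 6339 lower in UKE1 (6434 and 6107 after quantile normalization, 6538 and 6010 after median centring). Erythroid transcripts were among the largest differences: the embryonic globin HBE1 and the carbonic anhydrase CA1 were lower in UKE1, by 7.76 and 7.31 on the log2 scale (adjusted p = 2.8e-17 and 6.18e-17). Other large decreases, each of at least 64.2-fold as measured, were those of CRIPTO, the histidine decarboxylase HDC, TOM1L1, the steroid-synthesis enzyme CYP11A1, TRIB2, the blood group gene RHD, NPY1R and PSMD5. UKE1 had at least 79.6-fold more CRISP3, VNN1, TRPS1, CLEC9A, APP, GTSF1, the chromatin organiser SATB1, PLAC8, AADAT and the progenitor marker CD34. The lower level of many of these genes lay near the low end of the arrays, such as 2.55 for CRIPTO in UKE1 and 3.37 for TRPS1 in HEL, so their folds and order are not exact. JAK2 was 4.18-fold lower in UKE1 (adjusted p = 4.32e-12), NFE2 4.09-fold (adjusted p = 8.69e-12), GATA1 7.04-fold (adjusted p = 4.44e-13) and BCL2L1 3.29-fold (adjusted p = 2.5e-11), and MYB differed by 0.14 (adjusted p = 0.0506).

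Of 26 erythroid genes 23 were lower and 3 higher in untreated UKE1, also when adjusted over the list alone; EPB42 (-4.29) and KEL (-3.69) were lower, and AHSP (0.23), RHAG (1.32) and CA2 (1.91) higher (camera adjusted p = 4.15e-07, adjusted p = 0.0764 with an estimated correlation). G1/S and replication genes were higher in 34 of 37 and lower in 1, CCND3 (-0.92), with 35 higher when adjusted over the list alone. Among those higher were GINS2 (2.03), CDT1 (1.47), MCM6 (1.43) and E2F8 (1.40). Camera gave this list an adjusted p = 5.88e-10, and an adjusted p = 0.11 with an estimated correlation. Of 14 stem and progenitor surface genes 11 were higher and 2, THY1 (-2.87) and PROCR (-1.10), lower, also when adjusted over the list alone, with SPINK2 (4.06) and FLT3 (3.61) next to CD34 (adjusted p = 0.001, adjusted p = 0.0764 with an estimated correlation). Lymphocyte markers were higher in 14 of 20 and lower in 3, CD2 (-0.81), CD7 (-0.28) and GNLY (-0.76), likewise when adjusted over the list alone. CD3G (5.77), CD3D (4.84) and CD3E (3.61), the CD3 subunits of the T-cell receptor complex, were in front. For this list the camera adjusted p was 0.000636 (adjusted p = 0.11 with an estimated correlation). Granulocyte and monocyte genes were higher in 10 of 19 and lower in 4, AZU1 (-0.49), LYZ (-0.51), CD68 (-0.24) and MS4A3 (-4.04), the same when adjusted over the list alone, with CLEC7A (5.14), CSF1R (4.45) and ITGAM (2.18) higher (adjusted p = 0.041, adjusted p = 0.289 with an estimated correlation).

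Several further lists had a camera call between the untreated lines. Of 18 endoplasmic reticulum stress genes 16 were lower and 2, XBP1 (0.38) and SEL1L (0.52), higher, with PPP1R15A (-2.36), DNAJB9 (-2.10) and HYOU1 (-1.86) in front (adjusted p = 0.000167, adjusted p = 0.289 with an estimated correlation). Of 19 immediate early genes 15 were lower and 1, DUSP2 (0.25), higher, with JUN (-3.25) and FOSB (-2.11) the clearest (adjusted p = 0.000636, adjusted p = 0.124 with an estimated correlation). Of 16 cholesterol synthesis genes 12 were lower and 1, SREBF1 (0.31), higher, including SC5D (-2.00) and INSIG1 (-1.96), at an adjusted p = 0.00264 (adjusted p = 0.289 with an estimated correlation). MYC and ribosome biogenesis genes were lower in 20 of 27 and higher in 1, UTP20 (0.35), with NOP2 at -1.08 and NOP16 at -0.98 (adjusted p = 0.00264; adjusted p = 0.289 with an estimated correlation). Metallothioneins were lower in 6 of 8 and higher in 0, with MT1F (-1.94) and MT1G (-1.86) in front (adjusted p = 0.00311, adjusted p = 0.11 with an estimated correlation). For these 5 lists the counts were the same when adjusted over the list alone. Homologous recombination genes were higher in 16 of 23 and lower in 3, CHEK2 (-0.47), RPA2 (-0.70) and RAD50 (-0.74), with 17 higher when adjusted over the list alone (adjusted p = 0.0121, adjusted p = 0.527 with an estimated correlation), among them BRIP1 (1.52) and BLM (0.94). The media of the lines differed, so line and medium cannot be told apart, either in this comparison or in the difference between the responses.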

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

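These results were picked out by rules fixed in advance: a response that differs between the lines by the interaction test, or a signal in rows outside the genes tested. Groups of 3 arrays were too small to look for single arrays far from the others. The tests in this part were chosen before their results were seen, except that the split counts at an unadjusted p were added afterwards.

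While 386 genes changed in opposite directions, fewer than independent lists would give, the interaction was past the threshold for 4395 genes. In 100 relabellings, each a split of the arrays of a treatment between lines after removing each line's mean, only the real labelling gave as many (1 of 100, highest of the other splits 0). The other splits were a random draw from those possible. At an unadjusted p under 0.05, limma gave 6452 genes with the real labels and at most 3553 with any other split drawn. The real count thus exceeded that of every labelling drawn. Almost every other split possible places arrays of both lines in at least 1 group. A real difference then enters the spread and can lower the count, so the comparison does not measure chance.

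Among single genes, the difference (UKE1 response minus HEL response, log2) was 2.92 for KRT79, which fell in HEL from 9.51 to 6.78 and in UKE1 was low in both conditions (5.44 and 5.63). FAM86B2-DT, from a duplicated gene family, differed by 2.41, with a fall of 1.35 in HEL and a rise of 1.06 in UKE1. The testis-specific linker histone H1-6 differed by 2.11, AHNAK2 by 2.06 and DNAAF11, a gene of cilium assembly, by 2.04, each with its increase in UKE1 (2.11, 1.74 and 2.07). SOSTDC1 differed by -2.93, changing in opposite directions. ABCA6 and OR52N5 differed by -2.55 and -2.24; in HEL their untreated levels were 3.03 and 3.71, against 8.31 and 7.57 in UKE1; whether the low level limited a fall in HEL was not tested. SMARCA1 and SERPINB9 differed by -2.42 and -2.29, with increases in HEL and log2 changes of 0.03 and -0.06 in UKE1.

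Among gene lists, the median difference was -0.46 for interferon response genes, -0.41 for stem and progenitor surface genes, -0.28 for death receptor and caspase genes, -0.25 for G1/S and replication genes and -0.19 for p53 targets. It was 0.29 for metallothioneins, 0.25 for immediate early genes, 0.18 for NF-kappaB targets and 0.0925 for MYC and ribosome biogenesis genes. None of these 9 calls held with an estimated correlation.

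Rows left out of the gene tests also changed. They were tested in a separate fit of all 33297 rows, with the adjustment over those rows. Of 12083 rows with no gene listed, 1952 (16.2%) passed the threshold in HEL and 2279 (18.9%) in UKE1. In the fit of genes, 42.4% and 44.3% passed in these lines. Of 1754 rows with several symbols, 551 (31.4%) passed in HEL and 624 (35.6%) in UKE1.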

How the results depend on the processing

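All alternatives were set before the data were examined. No count of genes changed by more than 1.5 times under quantile normalization, median centring, the mean of a gene's rows, an intensity trend, array weights or fits of 6 arrays alone. Over the 12 fits without 1 array the counts of genes raised by ITF2357 were 3777 to 4127 in HEL and 3605 to 4085 in UKE1, and those of a differing response 3726 to 4245. With only genes above the median level, 3515 and 4082 genes were higher and lower in untreated UKE1, as fewer genes were tested; with all rows tested singly, 9253 and 9894 rows were. At an adjusted p under 0.01 the response differed for 2555 genes. Asking for a 2-fold change as well left 436 higher and 251 lower in HEL, 403 and 416 in UKE1, 275 changed the same way, 390 with a differing response, 553 with an average response, and 1351 higher and 1527 lower in untreated UKE1. Of the named genes 0 reversed, against 168 losses and 34 gains of a call, while 12302 comparisons stayed the same. Over all alternatives 91 list tests lost a call, 41 of them with an estimated correlation, and 68 gained one, 50 of them with fry; fry also turned 3 untreated comparisons that camera had not called downwards: CDK inhibitors (adjusted p = 0.0247), G2/M genes (0.0471) and antigen presentation genes (0.0471); the cause was not tested. Whether the replicate numbers pair the arrays stays open: deviations of same-numbered arrays of a line correlated at -0.0877 to 0.0645 in HEL and 0.0302 to 0.0348 in UKE1, those of untreated arrays across lines at -0.0143 to 0.1224, and 8 of 12 arrays, not every one, matched their own number best. With a replicate block 4024 genes rose and 3566 fell in HEL, 3920 and 3976 in UKE1, and 3899 responded differently. Without a detection flag, no level was tested against background.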

Other observations

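Several lists with no camera call in either drug comparison held genes that changed in the same direction in both lines, not always by the same amount. Of 18 histone deacetylase genes 8 rose and 2 fell in HEL, and 8 rose and 5 fell in UKE1 (camera adjusted p = 0.197 and 0.275). HDAC3 rose by 1.16 and 1.11, HDAC11 by 1.36 and 1.13 and SIRT2 by 0.71 and 0.64 in HEL and UKE1, while SIRT1 fell by 0.69 and 0.20. Of 17 chaperone genes 4 rose and 8 fell in HEL, and 3 rose and 6 fell in UKE1 (camera adjusted p = 0.499 and 0.394); DNAJB4 (1.06 and 0.74) and BAG3 (0.90 and 0.63) rose in both. JAK-STAT components went both ways, 7 up and 5 down of 19 in HEL and 7 up and 10 down in UKE1 (camera adjusted p = 0.697 and 0.757), with PTPN1 at 0.72 and 0.79 and the ubiquitin ligase CBL at 1.24 and 0.47. STAT5 targets did likewise, 6 up and 8 down of 20 in HEL and 8 up and 9 down in UKE1 (camera adjusted p = 0.655 and 0.713): PIM1 fell by 0.79 in HEL and rose by 0.37 in UKE1, and PIM2 fell by 0.59 and rose by 0.82.

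Erythroid genes rose in 10 and fell in 5 of 26 cases in HEL, and rose in 5 and fell in 6 in UKE1 (camera adjusted p = 0.52 and 0.68), with ALAD up by 0.99 and 0.90 and XK down by 0.70 and 0.57 on the log2 scale. Antigen presentation genes rose in 7 and fell in 4 of 13 cases in each line (camera adjusted p = 0.168 and 0.779), with PSMB9 at 0.70 and 0.61 and HLA-DMB at 0.42 and 0.50. Of 7 CDK inhibitors 3 rose and 0 fell in HEL, and 3 rose and 1, CDKN1B (-0.41), fell in UKE1 (camera adjusted p = 0.203 and 0.394). Neuronal genes rose in 3 and fell in 1 of 21 cases in HEL, and rose in 5 and fell in 1 in UKE1 (camera adjusted p = 0.645 and 0.49), with SYP at 0.89 and 1.00. Endoplasmic reticulum stress genes rose in 5 and fell in 6 of 18 cases in HEL and in 7 and 4 in UKE1 (camera adjusted p = 0.974 and 0.515), including SESN2 at 0.73 and 0.91. NF-kappaB targets rose in 4 and fell in 9 of 21 cases in HEL and in 7 and 6 in UKE1 (camera adjusted p = 0.161 and 0.903), with NFKB2 at 1.06 and 1.38 and NFKB1 at -0.89 and -1.02. Markers of other blood and tissue cells were also not called: granulocyte and monocyte genes (2 rose and 3 fell of 19 in HEL, 4 and 8 in UKE1, with CSF1R at -1.44; camera adjusted p = 0.851 and 0.363), lymphocyte genes (1 rose and 3 fell of 20 in HEL, 2 and 8 in UKE1; camera adjusted p = 0.52 and 0.116), and fibroblast and endothelial genes (2 rose and 3 fell of 14 in HEL, 2 and 4 in UKE1; camera adjusted p = 0.794 and 0.345). Adjusted over the list alone, the counts were 10 up and 6 down for erythroid and 8 up and 6 down for JAK-STAT genes, 4 up and 10 down for NF-kappaB targets and 2 up and 1 down for granulocyte genes in HEL, 2 up and 9 down for lymphocyte genes in UKE1, and 2 and 4 up with 0 down for neuronal genes in HEL and UKE1; those of the other lists here were the same.

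The tests in the next paragraphs were chosen before their results were seen, except 1 check of neighbouring genes, named as added, and the split counts at an unadjusted p. The lines were closer to each other with ITF2357 than without it: over the genes tested, the mean r of 9 pairs of arrays across lines was 0.901 with drug and 0.893 without, and the lowest treated pair (0.899) exceeded the highest untreated pair (0.894). A change common to both lines could raise r but would leave the distance between lines as it was. The mean squared log2 difference between lines, with replicate noise subtracted, was 0.856 with drug and 0.920 without. Their ratio was 0.930 (0.925 to 0.937 over 12 fits without 1 array). A common change alone would not give this smaller distance, but whether it added to the higher r was not tested. A narrower range of treated values does not account for the smaller distance either, since the variance over genes had a ratio of 0.995 (0.984 to 1.01 without 1 array). A convergence of the lines under the drug may underlie this, as a hypothesis; an effect of normalization was not tested and stays open.

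Neighbouring genes changed slightly alike: the average responses of 18339 neighbouring pairs correlated at r = 0.065, above the highest of 1000 orders shuffled within chromosomes (0.0285). Leaving out 2076 pairs whose symbols share their 3 leading characters, as many related genes do, lowered r to 0.0435, still above the highest shuffled order (0.0273). Such pairs therefore gave part but not all of the correlation. Related neighbours with other leading characters stayed in, so how much similar probes add stays open. Removing a trend of the change on expression level left r at 0.065. The change of a gene in HEL correlated with that of its neighbour in UKE1 at r = 0.042 (highest shuffled order 0.0276), in line with a response shared by neighbours in both lines. With same-lettered pairs left out in an added check that r was 0.0288, which 1 of 1000 shuffled orders reached (highest 0.0298); overlapping genes measured by the same probes stay open.

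For the drug effect in HEL, 1 of the 10 splits of the 6 arrays, the real one, gave 7816 genes, and the highest of the others gave 0; for UKE1 the counts were 8160 and 0, and between the untreated lines 12471 and 0. At an unadjusted p under 0.05 limma gave 8866, 9165 and 12926 genes with the real split and at most 856, 477 and 564 with another. These 10 splits are too few for a share under 0.05. Every other split also mixes drug and control arrays, or the lines, within a group. A real difference then enters the spread and lowers the count, so those counts do not measure chance. For both lines together, 100 relabellings within lines were used, the real one and others drawn at random from those possible. Only the real one gave 4968 genes changed the same way (highest other drawn 0, and 280 against 5586 at an unadjusted p under 0.05). It was also the only one with 9387 genes of an average response (highest other drawn 3646). The labelling that swaps drug and control in 1 line was not drawn. By construction it gives 386 genes changed the same way and 4395 with an average response. The real counts exceeded those of every labelling drawn. All the others drawn mix drug and control arrays within a group in at least 1 line. For the same reason they do not measure chance.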
